A study of Mus musculus with 2 samples.

How the data were processed

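Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in facial prominences of mouse embryos of strain B6NCrl at 12.5 days of gestation. The labels describe 1 group with 2 biological replicates, a pool of 120 embryos (replicate 1) and a pool of 88 embryos (replicate 2), each of mixed sex. There was no second tissue, stage or treatment, so no contrast between groups was tested. The 2 pools are separate collections of embryos, and the spread between them was the only replicate error.

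The files used here were the authors' 12 peak lists on the mm10 assembly. They hold no read counts, so the sequencing depth is unknown here and no interval or limit that needs it is given. Per library there was a list of peaks kept in pseudoreplicates (random splits of a library's own reads), a list ranked by the irreproducible discovery rate (IDR) and a list cut at an IDR threshold. For the series there were lists of peaks replicated in both libraries, of pooled pseudoreplicated peaks, of IDR-thresholded peaks, of conservative IDR-thresholded peaks, and 2 ranked lists. Each deposited peak carries a fold enrichment (a linear ratio, at the summit), whose control is not given in the sources used here, and −log10 of a p-value and of a q-value, all by the authors' peak caller. The lowest deposited −log10 p was 2.00 in each list. The peak caller, the aligner, their versions and whether reads were shifted for the Tn5 offset are not given in the sources used here. The thresholded and replicated lists also derive from a further file whose content is not stated, and they hold 0 peaks outside the 21 chromosomes, where the ranked lists hold some. Fold enrichments and −log10 p are the authors' values per peak. They served to describe and rank peaks within a list, and fold enrichments of shared regions were correlated between the libraries. No difference between libraries was tested on them.

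Deposited intervals repeat with up to 9 summits in the filtered lists, so peaks that overlapped by at least 1 bp were joined into regions. A region kept its highest fold enrichment and the summit of its peak with the highest −log10 p. The list replicated in both libraries was the main list, and each library's own pseudoreplicated list gave the value per replicate. The lists for the series hold peaks of both libraries together. A region of the main list need therefore not be in either library's own list. The promoters of Pax7 and Cdh5, for example, were open in the main list and in neither library's own list. Coordinates were checked against GRCm38 sequence and 0 peaks ran past a chromosome end. Genes were taken from GENCODE release M21, with 21938 protein-coding and 13374 long non-coding genes.

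A region was called a promoter region when its summit lay within 500 bp of a transcription start site (TSS) of a protein-coding or long non-coding gene, otherwise exonic, intronic or intergenic. The promoter of a gene was called open when a region overlapped 500 bp either side of any of its TSSs. A gene whose promoter is not called open has no listed peak there, which does not show that the DNA is inaccessible. Distal regions had a summit over 2500 bp from every protein-coding TSS and were given to the gene of the nearest TSS within 1 Mb, which need not be the gene they act on. The territory of a gene is the stretch of genome nearest to its TSSs. Regions of the 2 libraries counted as shared when they overlapped by at least 50% of the shorter one, and chance sharing came from 100 random placements.

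The 18 gene lists, the 34 motif consensuses, the rule for named genes and the tests were fixed before the data were examined. Open promoters were compared by two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 18 lists, beside 10000 random lists matched on decile of promoter CpG content (observed over expected). Numbers of distal regions were compared as the mean of log2(n + 1) against 10000 random lists matched on decile of territory length. That permutation test was two-sided and could give no p below 0.0002. Motifs were counted in windows of 100 bp either side of distal summits and compared by Fisher's exact test with as many windows outside every deposited peak, over 2500 bp from a TSS, matched on GC decile. Pairs of an E-box core (CAGATG) and a homeodomain core (TAATT or its complement) were counted by start-to-start offset up to 40 bp on either side, 142 arrangements in all. Genes, regions and windows are not biological replicates, so these p-values describe this tissue's lists. Odds ratios carry 95% Woolf intervals, shares 95% Wilson or exact intervals, and these cover counting error only.

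Named genes were the 15 with the most distal regions, in each list up to 4 members with the most distal regions and up to 4 without a region at a TSS, the genes nearest the 10 regions of highest fold enrichment, the Hox clusters and Dlx pairs, and the motifs with the 8 highest and 5 lowest odds ratios. Alternatives tried were the conservative IDR list, each library alone, other overlap rules, a promoter window of 1000 bp, the 5'-most TSS only, assignment within 100 kb, flanking background windows and clusters without flank. Matching on 50 bins in place of 10, of territory or of GC, was chosen after seeing the data.

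The statistics were tested on simulated data. For distal regions, 10 of 10 lists of 20 genes with 2-fold higher counts and 0 of 10 unchanged lists passed the threshold among 21938 genes. These counts were Poisson numbers at 1 rate per territory decile, and the real counts spread more widely. In the decile of longest territories the mean was 3.74, the 99th percentile 19, and 22.5% of genes had none. Real bone genes (mean 2.5 against 1.14 in matched lists) and cartilage genes (3.76 against 1.72) did not pass. The simulation thus does not give the power for these data. For promoters, 10 of 10 lists with 20% of genes open passed, and 0 of 10 lists with 62% open. Of motifs planted in 2 of 100 windows 17 of 17 were recovered, and 1 of 17 motifs not planted also passed. The planted pair was recovered at its arrangement and at 0 of the other 141. For motifs and pairs both sets of simulated windows were uniform random bases, without the base composition or repeats of the genome. Their counts therefore do not give the error rate for these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and BLAST+ 2.17.0 were used.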

Results

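Chromatin accessibility was profiled in the facial prominences, the swellings that form the upper and lower jaw, midface and nose, of mouse embryos at 12.5 days of gestation. The data collected were peak lists from 2 libraries of 1 group, made from pools of 120 and 88 embryos. Replicate 1 had 50155 deposited peaks in 28746 regions covering 16.8 Mb, and replicate 2 had 45959 peaks in 26002 regions covering 15.2 Mb. The list replicated in both libraries, used as the main list, held 72634 peaks in 38315 regions covering 23.4 Mb, more than either library's own list. It holds peaks of both libraries together, so a result in the main list is not by itself a result in each pool. The conservative list held 13237 regions. The labels state no hypothesis, and the comparisons below describe which genes and sequences the accessible regions of this tissue lay at and how far the 2 pools matched.

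Strong accessible regions were found in both pools and weak ones often in 1 pool. Of the replicate 1 regions, 61.4% (17645 of 28746, 95% Wilson interval 60.8 to 61.9%) were shared with replicate 2, and 68.3% of the replicate 2 regions (17759 of 26002, 67.7 to 68.9%) were shared with replicate 1. Random placement gave means of 0.793% and 0.878%. With each library's regions split into 4 equal bins by −log10 p, 99.7% of replicate 1 and 99.8% of replicate 2 regions were shared in the top bin, against 19.7% and 27.5% in the lowest. Across 18224 shared pairs of regions the authors' fold enrichments were correlated (Spearman rho 0.79, Pearson r 0.80 on the log2 scale). These correlations are across regions, which are not independent replicates.

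Promoters made up a large part of the open chromatin. In the main list 39.0% of regions (14927 of 38315) were promoter regions, a class that covers 2.53% of the assembled genome, a 15.4-fold difference. Introns held 29.4% of regions, intergenic DNA 27.2% and exons 4.44%, against 39.5%, 54.5% and 3.51% of the genome. The promoter share was 47.1% in replicate 1 and 51.8% in replicate 2 (SD between replicates 3.28 percentage points), 75.4% in the conservative list, and went from 12.3% in the lowest to 84.2% in the highest of 4 equal bins of −log10 p. The share differed more between lists than between the pools.

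Promoters of facial patterning genes were open in large numbers, and those of macrophage, liver, germ cell and olfactory receptor genes mostly had no region. Of 21938 protein-coding genes, 13638 (62.2%) had an open promoter, and 12718 (58.0%) and 12664 (57.7%) had one in replicates 1 and 2 alone. Among cranial neural crest and facial mesenchyme transcription factors 42 of 50 were open (84.0%, exact 95% interval 70.9 to 92.8%, Fisher's exact test, adjusted p = 0.00336). Among facial signalling and orofacial cleft genes 37 of 39 were open (94.9%, 82.7 to 99.4%, Fisher's exact test, adjusted p = 1.21e-05), Gli2, Gli3, Chd7 and Spry2 included. Both shares were near those of promoters of the same CpG decile, at 85.9% (permutation, adjusted p = 0.952) and 85.6% (adjusted p = 0.196), although with the 5'-most TSS only the transcription factors lay below them (70% against 83.5%, adjusted p = 0.0225). The exceptions in the signalling list were Shh (chromosome 5, 28456815 to 28467256) and Fgf8 (chromosome 19, 45736798 to 45742915), ligands secreted by facial epithelia, which had no region at a TSS in either library. In the transcription factor list the 8 without one included Dlx3, Hand1, Lhx6 and Nr2f1, of which Dlx3 and Nr2f1 had one in replicate 1's own list. The transcription factor call was lost in the conservative list (56% of members, Fisher's exact test, adjusted p = 0.322) and with the 5'-most TSS only (70%, adjusted p = 0.0828), and the signalling call in the conservative list (64.1%, adjusted p = 0.0653).

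Promoters of ectoderm, macrophage, hepatocyte, male germ cell and olfactory receptor genes were open less often than those of other genes. Of surface ectoderm and periderm genes, 11 of 27 promoters were open (40.7%, 22.4 to 61.2%, Fisher's exact test, adjusted p = 0.0418), below the 64.9% of promoters of the same CpG decile (permutation, adjusted p = 0.0189). Grhl2, a regulator of epithelial identity, and the adhesion genes Epcam and Perp were open, whereas Grhl3 and the claudins Cldn4, Cldn6 and Cldn7 had no region at a TSS in the main list (Cldn4 had one in replicate 2's own list). A further claudin, Cldn3, chosen after its values were seen, was open in the main list and in each library. Macrophage genes had 0 of 15 open promoters (Fisher's exact test, adjusted p = 2.77e-06, CpG-matched 19.9%, adjusted p = 0.188), among them Adgre1, Aif1, C1qa and C1qb. Hepatocyte genes had 1 of 20 open (5%, adjusted p = 1.09e-06 by Fisher's exact test, CpG-matched 29.7%, adjusted p = 0.0245), with Afp, Ahsg, Alb and Ambp without a region at a TSS. Male germ cell genes had 3 of 15 open (20%, 13.3% and 26.7% in replicates 1 and 2 alone, adjusted p = 0.00483 by Fisher's exact test, CpG-matched 48.2%, adjusted p = 0.0189). Of 1093 olfactory receptor genes 4 were open (0.366%, with 5 and 1 in replicates 1 and 2 alone). The CpG-matched share was 13.3% (permutation, adjusted p = 0.0018, the smallest it can give here). The difference from CpG-matched promoters was lost for hepatocyte genes in replicates 1 and 2 alone (permutation, adjusted p = 0.0924 and 0.116), in the conservative list (0.337) and with the 5'-most TSS (0.367). For male germ cell genes it was lost in replicate 2 alone (permutation, adjusted p = 0.305), in the conservative list (0.0788) and with the 5'-most TSS (0.0814).

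Bone genes were open in 4 of 14 cases (28.6%, Fisher's exact test, adjusted p = 0.0226). Runx2, a master regulator of osteoblasts, and the collagen genes Col1a1 and Col1a2 were among the open ones, while the mineralised-matrix genes Bglap, Bglap2, Dmp1 and Ibsp were not. Sp7, also an osteoblast regulator, had no region at a TSS in the main list or in either library. The open and closed members thus did not divide into regulators and matrix genes. Erythroid genes (6 of 18, 33.3%, adjusted p = 0.0241), cardiomyocyte genes (5 of 15, 33.3%, in replicates 1 and 2 alone 3 and 4, adjusted p = 0.0423) and photoreceptor genes (4 of 15, 26.7%, adjusted p = 0.013) also lay below other genes by Fisher's exact test. Of these lists bone, erythroid, cardiomyocyte and photoreceptor genes did not differ from CpG-matched promoters (29.9%, 33.9%, 43.4% and 41.2% open, lowest adjusted p = 0.562 by permutation). The calls for ectoderm, bone, erythroid and cardiomyocyte genes were lost with a 1000 bp promoter window (Fisher's exact test, adjusted p from 0.0509 to 0.0679). The erythroid call was also lost in replicate 1 alone (38.9%, Fisher's exact test, adjusted p = 0.168), and the cardiomyocyte and photoreceptor calls in the conservative list (20% each, adjusted p = 0.0507).

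Cartilage (12 of 17), skeletal muscle (10 of 20), endothelial (8 of 18), neuronal (15 of 18) and neural crest glia and melanoblast genes (7 of 12) did not pass (Fisher's exact test, adjusted p from 0.112 to 0.774). Among these, Col9a2, Acta1, Erg, Dcx and Dct had no region at a TSS in the main list. In each library alone 4 of 12 glia and melanoblast genes were open (33.3%), which did not pass either. Muscle and endothelial genes passed as lower than other genes in each library alone, at 25% and 30% for muscle and 27.8% and 16.7% for endothelium in replicates 1 and 2 (Fisher's exact test, adjusted p from 0.00127 to 0.0296), and in the conservative list (5% and 5.56%). Endothelial genes also lay below CpG-matched promoters in replicates 1 and 2 alone (permutation, adjusted p = 0.0338 and 0.0012). In the conservative list muscle, endothelial, erythroid and neuronal genes did (permutation, adjusted p from 0.0009 to 0.0298). Housekeeping genes were open in 16 of 17 cases (94.1%, Fisher's exact test, adjusted p = 0.011, CpG-matched 87.4%, adjusted p = 0.72), with Ubc the exception in the main list and open in replicate 2.

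**Figure D1:**
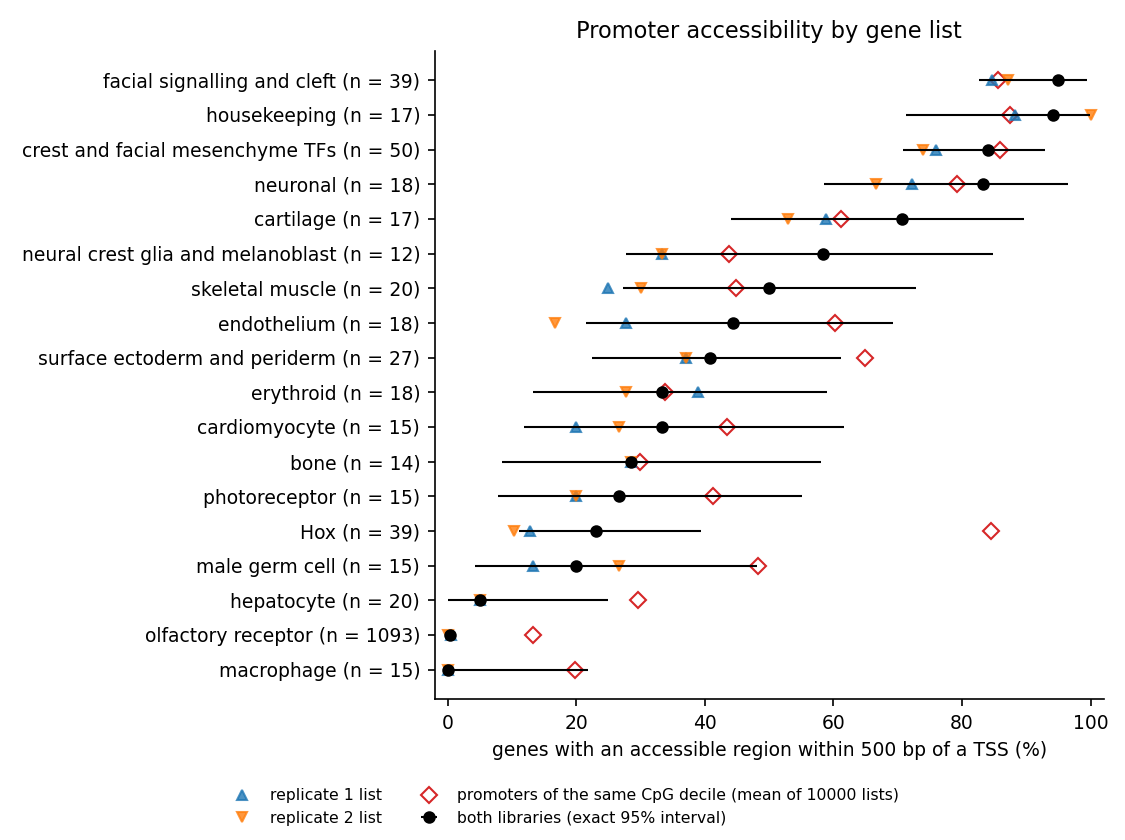
Share of genes in each of 18 lists with an accessible region within 500 bp of a TSS (x axis, percent). Black points are the main list with exact 95% intervals, triangles each library's own list, and red diamonds the mean of 10000 lists matched on CpG decile. Hox genes stand farthest below their matched promoters, at 23.1% against 84.4%.

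Distal accessible regions were more numerous at the 2 lists of facial genes than at random lists matched on territory length. Apart from Hox genes, no list made up of developmental regulators of other tissues was compared. Whether the excess is particular to facial genes was therefore not tested. The main list had 21098 distal regions, 55.1% of all, replicates 1 and 2 alone had 13581 (47.2%) and 11150 (42.9%), and the conservative list had 2875 (21.7%). Neural crest and facial mesenchyme transcription factors had a median of 3 distal regions, against a mean median of 0.98 in matched lists, and differed by 0.86 on the log2(n + 1) scale (226 regions at 50 genes, 7 genes with none, permutation, adjusted p = 0.0012). Facial signalling genes had a median of 4 against 1.29 and differed by 0.88 (196 regions at 39 genes, 5 with none, permutation, adjusted p = 0.0012, the smallest it can give here). Both medians were 2 in each library alone, against 0.468 and 0.246 for transcription factors and 0.756 and 0.548 for signalling genes in lists matched in replicates 1 and 2, and both were 0 in the conservative list. In the lists of replicates 1 and 2 alone the differences were 0.75 and 0.72 for transcription factors and 0.66 and 0.83 for signalling genes (permutation, each with adjusted p = 0.0012). They were smaller in the conservative list, at 0.25 (permutation, adjusted p = 0.0144) and 0.34 (adjusted p = 0.0018).

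Single members showed how this was spread. Among the transcription factors Pbx1 (chromosome 1, 168119364 to 168432270), a cofactor of homeodomain proteins, had 24 distal regions, the nuclear receptor Nr2f2 14, and Meis1 and the cleft-associated Mn1 13 each, against medians of 3 for genes in the territory decile of Pbx1, Nr2f2 and Meis1 and 1 for that of Mn1. The territories of Pbx1, Nr2f2 and Meis1 (1050, 1307 and 989 kb) were longer than their decile's median of 503 kb, so territory length was not held equal. Nr2f2 had its regions although no region lay at its TSSs, and Nr2f1 had 12 and no promoter region. Among signalling genes the Hedgehog effectors Gli2 and Gli3 had 16 and 15, the chromatin remodeller Chd7 14 and the FGF antagonist Spry2 13. Single libraries held fewer, in replicates 1 and 2 alone 11 and 8 at Pbx1, 8 and 5 at Nr2f2, 7 and 11 at Meis1, 10 and 6 at Mn1 and 11 and 8 at Nr2f1. They held 12 and 6 at Gli2, 6 and 6 at Gli3, 13 and 13 at Chd7, and 6 and 6 at Spry2. The conservative list held 0 at Pbx1. Shh (1 and 2 in replicates 1 and 2 alone) and Fgf8 (2 and 2) had 3 distal regions each, against medians of 3 and 0 in their territory deciles.

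With the nearest-gene assignment and territory deciles, no other list except housekeeping genes passed as having more distal regions than matched lists. Cartilage genes differed by 0.50 (adjusted p = 0.0762 by permutation) and bone genes by 0.54 (adjusted p = 0.0518), and neither passed, although cartilage did in replicate 2 alone (0.49, adjusted p = 0.0382). Of the 64 regions in the cartilage list most lay at transcription factors of chondrocytes, with 19 at Sox5, 15 at Sox6 and 15 at Sox9 (chromosome 11, 112782224 to 112787760). Among matrix genes Col9a1 had 4 (2 and 3 in replicates 1 and 2 alone) and Matn1 had 2 (9 and 2), and Col9a2, Col9a3 and Matn4 had 0, although Matn4 had 1 in replicate 2 alone. In replicates 1 and 2 alone Sox5 had 7 and 6, Sox6 had 10 and 5, and Sox9 had 14 and 8. In the bone list Runx2 had 8 (2 and 1 in replicates 1 and 2 alone), Col1a1 had 7 (6 and 5), Col1a2 had 7 (5 and 6) and Sp7 had 5 (2 and 3). Neuronal genes differed by 0.43 (adjusted p = 0.118 by permutation), with 6 regions each at Stmn2 (3 and 0 in replicates 1 and 2 alone) and Syt1 (1 and 1). Endothelial genes differed by 0.33 (adjusted p = 0.211 by permutation), of which Cdh5, the endothelial cadherin, held 11 of 33 regions (8 and 11 in replicates 1 and 2 alone). Muscle, macrophage, erythroid, photoreceptor, cardiomyocyte, germ cell, hepatocyte, ectoderm and glial lists differed by −0.17 to 0.28 and did not pass (permutation, adjusted p from 0.173 to 0.889). Macrophage genes passed in replicate 2 alone (0.40, permutation, adjusted p = 0.0306), against 0.24 in replicate 1 alone. Ectoderm and hepatocyte genes had slightly fewer regions on average than matched lists (0.704 against 0.756, and 0.6 against 0.705) with differences of 0.05 and 0.02 on the log2 scale. Epcam had 5 distal regions (0 and 2 in replicates 1 and 2 alone), Grhl2 had 3 (0 and 2), and Grhl3 and Perp 2 each. Counting all regions within 100 kb of a gene, cartilage, bone, muscle and endothelial genes passed (0.66, 0.72, 0.56 and 0.60, permutation, adjusted p from 0.0297 to 0.0381). Bone genes also passed with 50 bins of territory (0.54, permutation, adjusted p = 0.0461).

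Housekeeping genes had a higher mean of log2(n + 1) by 0.39 (adjusted p = 0.0288 by permutation), with 9 of their 19 regions at Ywhaz (3 and 3 in replicates 1 and 2 alone) and 3 each at Actb (0 and 1) and Ubc (2 and 1). This was not found in either library alone (0.19 and 0.13, permutation, adjusted p = 0.241 and 0.541) or in the conservative list (0.06, adjusted p = 0.834), nor when all regions within 100 kb were counted (0.47, adjusted p = 0.0928). Olfactory receptor genes had fewer distal regions, by 0.19 (a difference of −0.19, adjusted p = 0.0012 by permutation, −0.14 and −0.12 in replicates 1 and 2 alone), and 1049 of 1093 had none. The exceptions with the most were Olfr161 with 18 (14 and 9 in replicates 1 and 2 alone), in a territory of 1064 kb, and Olfr1423 with 6 (5 and 3).

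**Figure D2:**
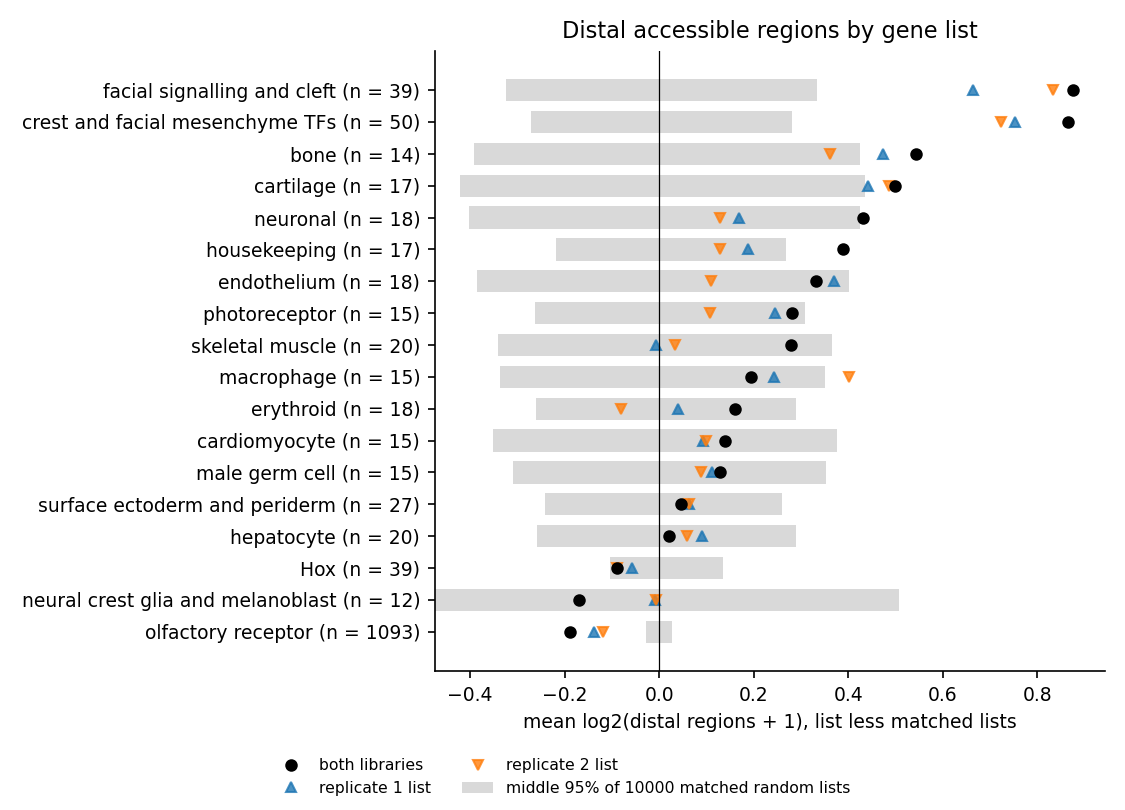
Mean log2(distal regions + 1) of each list less that of matched lists (x axis). Black points are the main list, triangles each library's own list, and grey bars hold the middle 95% of 10000 lists matched on territory decile. Facial signalling genes (0.88) and crest transcription factors (0.86) lie outside their bars in the main list and in each library.

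The genes with the most distal regions genome-wide included developmental regulators and adhesion genes. Tenm4, a teneurin adhesion protein (chromosome 7, 96171246 to 96911093), had 33 distal regions, with 19 and 17 in the lists of replicates 1 and 2. Zmiz1, a transcriptional coregulator (chromosome 14, 25459185 to 25666743), had 31 (23 and 17), and Zfp36l1, an RNA-binding protein (chromosome 12, 80107754 to 80113013), had 29 (18 and 13). Zfp608 followed with 26, Cdh4 and Dnm3 with 25 each, Auts2 and Pbx1 with 24 each, and Nfib, Rapgef5 and Tenm3 with 23 each. Efna5, Gse1, Med13l and Mycn had 22 each. In replicates 1 and 2 alone the counts of these 12 genes were lower, from 8 at Efna5 to 19 at Auts2 and from 6 at Efna5 to 19 at Dnm3. All 15 genes lay in the territory decile with a median of 3 distal regions. The median territory of that decile was 503 kb, and those of the 15 genes were from 376 kb at Gse1 to 1939 kb at Auts2. Territory length was thus not held equal in this comparison. Within 100 kb of the gene's 5'-most TSS there were from 0 distal regions, at Dnm3 and Auts2, to 14 at Zmiz1. Nfib encodes a nuclear factor I (NFI) protein, and Mycn a transcription factor of progenitor growth.

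Hox promoters were mostly without an accessible region, and the Hox clusters held fewer regions for their length than the Dlx pairs. Hox genes give positional identity along the trunk and posterior arches, while Dlx genes pattern the jaw-forming arch. Only 9 of 39 Hox promoters were open (23.1%, exact interval 11.1 to 39.3%), against 62.2% of other genes (Fisher's exact test, adjusted p = 4.36e-06) and 84.4% of promoters of the same CpG decile (permutation, adjusted p = 0.0018). In replicates 1 and 2 alone 5 and 4 were open (12.8% and 10.3%). The open ones were Hoxa1, Hoxa7 and Hoxa13, Hoxc5 and Hoxc10, which share 1 region on chromosome 15 (102966858 to 102967471), and Hoxd1, Hoxd9, Hoxd10 and Hoxd13. None of the 10 Hoxb genes was open. These 9 were named after their values were seen. Of the 39 genes 37 had no distal region, Hoxb4 had 2 (0 and 0 in replicates 1 and 2 alone) and Hoxd4 had 1 (1 and 0). The list did not differ from matched lists (a difference of −0.09, adjusted p = 0.25 by permutation). Counting all regions within 100 kb of a gene the difference was −0.35 (adjusted p = 0.0549 by permutation) and did not pass either.

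Per 100 kb, with 100 kb on either side, there were 1.64 regions at Hoxa, 0.802 at Hoxb, 1.27 at Hoxc and 2.70 at Hoxd, against 1.41 genome-wide. There were 3.66 at Dlx1-Dlx2 (chromosome 2, 71428113 to 71646754), 4.86 at Dlx3-Dlx4 (chromosome 11, 95020119 to 95246263) and 4.11 at Dlx5-Dlx6 (chromosome 6, 6763334 to 6982085). These windows also count regions at open promoters of neighbouring genes, named after their values were seen. They were Lnpk and Mtx2 at Hoxd, Metap1d at Dlx1-Dlx2, Pdk2 and Itga3 at Dlx3-Dlx4 and Sdhaf3 at Dlx5-Dlx6, among others. Of the 11 regions at Dlx3-Dlx4, 2 lay between its first and last gene. Between the first and last gene, without flank, there were 1 region in Hoxc, 2 in Hoxb, 4 in Hoxa and 5 in Hoxd, and 5 within the much shorter Dlx5-Dlx6 interval (26.7 per 100 kb). In replicates 1 and 2 alone they were 1 and 1 in Hoxc, 0 and 0 in Hoxb, and 2 and 1 in Hoxa. Hoxd held 3 and 1, and Dlx5-Dlx6 held 3 and 4. Regions within Hox clusters had the authors' fold enrichment from 2.37 to 4.44. The median over all deposited peaks of the main list was 3.31. Regions keep their highest value, and their medians in 4 equal bins of −log10 p were 2.67, 3.38, 4.43 and 7.96. The conservative list held 0 regions within the Hox clusters and 0 within Dlx3-Dlx4, 1 within Dlx5-Dlx6 and 2 within Dlx1-Dlx2. No test was made of these densities. In replicates 1 and 2 alone the Hox densities were from 0.267 to 1.68 and the Dlx densities from 2.29 to 3.66, against 1.05 and 0.954 genome-wide.

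**Figure D3:**
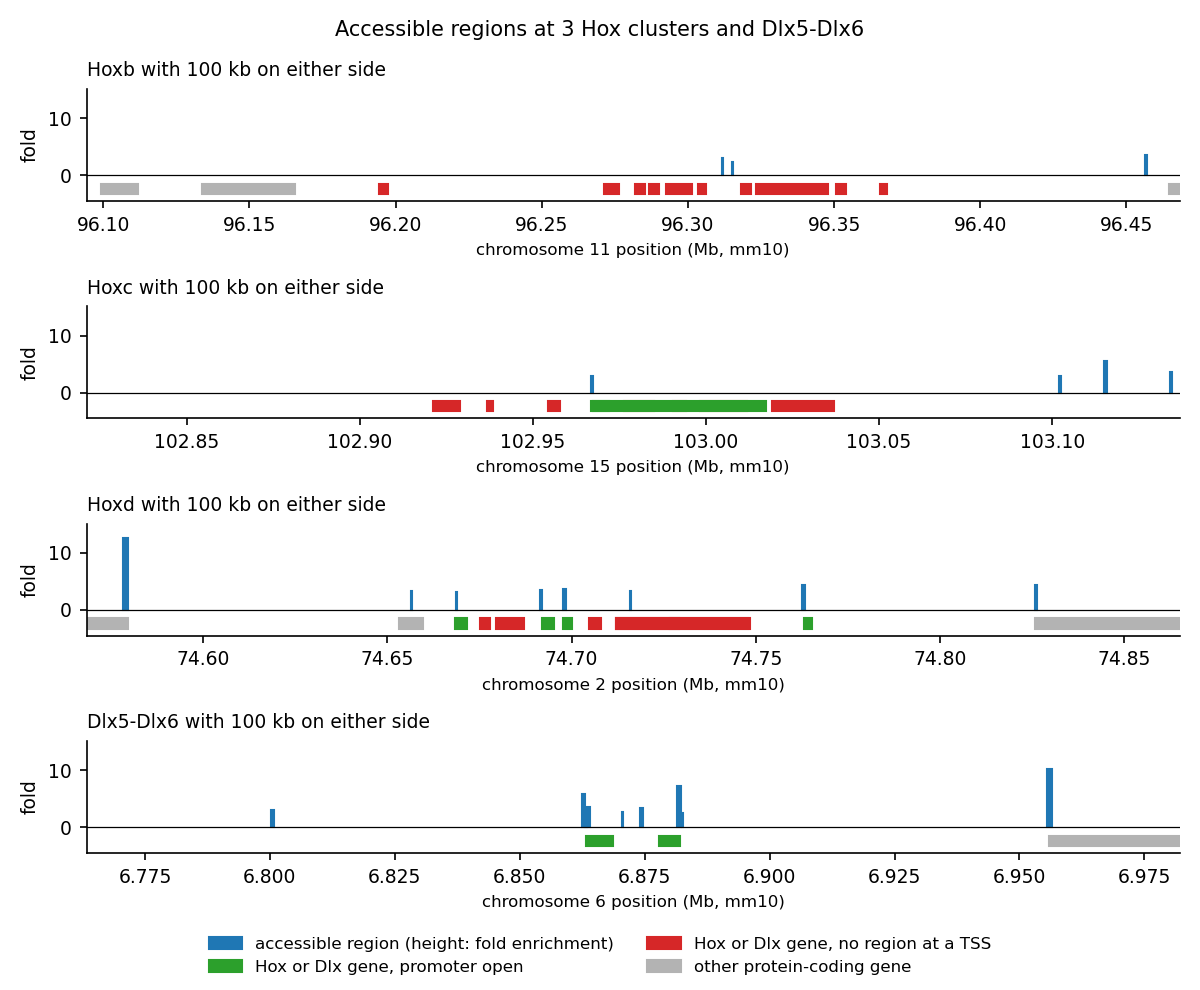
Accessible regions of the main list (blue, height is the authors' fold enrichment) across Hoxb, Hoxc, Hoxd and Dlx5-Dlx6 with 100 kb on either side (x axis, Mb, mm10). Boxes below are protein-coding genes, green for Hox or Dlx genes with an open promoter, red for those without and grey for others. Hoxb holds 3 regions in 374 kb and Dlx5-Dlx6 holds 9 in 219 kb.

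Binding motifs of CTCF, NFI and RFX factors and of E-box proteins were more frequent in distal than in GC-matched windows. The NFI and RFX motifs were rare all the same, in 0.147% and 0.450% of distal windows. The consensus of CTCF, the insulator protein, occurred in 3.37% of 21097 distal windows and 0.185% of GC-matched windows (odds ratio 18.9, 95% interval 13.7 to 26.0, Fisher's exact test, adjusted p = 6.57e-162). The odds ratio was 11.7 (8.36 to 16.4) in replicate 1 alone, 20 in replicate 2 alone and 29.6 in the conservative list. The NFI palindrome had an odds ratio of 6.21 (2.41 to 16.0, 31 against 5 windows, Fisher's exact test, adjusted p = 3.35e-05), the RFX motif 5.61 (3.35 to 9.40, 95 against 17, adjusted p = 1.13e-13) and SP/KLF 2.09 (1.81 to 2.41, adjusted p = 1.37e-23). The RFX odds ratio was 11.4 and 6.59 in replicates 1 and 2 alone, 21.1 in the conservative list and 13.0 against windows 1000 bp from the same summits, and that of SP/KLF was 4.10 in the conservative list and 4.91 against those windows. The myogenic-type E-box, which several mesenchymal basic helix-loop-helix proteins also bind, was present in 18.7% against 10.4% of windows (odds ratio 1.98, 1.87 to 2.09, Fisher's exact test, adjusted p = 3.42e-128). NRF1 (2.45, 1.13 to 5.31, 22 against 9 windows, Fisher's exact test, adjusted p = 0.0555) and the paired-type homeodomain dimer (2.43, 1.01 to 5.86, 17 against 7, adjusted p = 0.109) did not pass, and REST rested on 1 window against 0. NRF1 passed in replicates 1 and 2 alone (3.0 and 4.61, Fisher's exact test, adjusted p = 0.0480 and 0.0022), and the paired-type dimer in replicate 2 alone (10 windows against 0, adjusted p = 0.0039), with 5 against 6 in replicate 1 alone.

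In all, 16 of 34 motifs were more frequent in distal windows, 0 less frequent and 18 did not pass. The motifs with the lowest odds ratios were those of HNF4 (0.70, Fisher's exact test, adjusted p = 0.167), GATA (0.83, adjusted p = 0.117), HOX13-type (0.85, adjusted p = 0.0577) and PBX proteins (0.89, adjusted p = 0.588), and HNF1, which was found in no window of either kind. The GATA motif passed as less frequent in replicate 2 alone (0.66, Fisher's exact test, adjusted p = 0.0039) and in the conservative list (0.40, adjusted p = 0.00661), and with 50 bins of GC (0.76, adjusted p = 0.0133). In replicate 2 alone HNF4 and PBX motifs lay above 1 (1.25 and 1.05). Among the others, chosen after their values were seen, homeodomain TAATTA had an odds ratio of 1.75 (3.47% against 2.01%, Fisher's exact test, adjusted p = 3.09e-19), RUNX 1.80 (adjusted p = 1.3e-14, lost in the conservative list at 1.38) and the TWIST-type E-box 1.51 (12.6% against 8.76%, adjusted p = 5.3e-37). TFAP2, SOX and LEF/TCF consensuses did not pass (1.12, 1.12 and 1.03), although SOX did in replicate 2 alone (1.47) and with 50 bins of GC (1.26). Against windows 1000 bp from the same summits, with a mean GC of 45.3% against 53.7% in the distal windows, the homeodomain motif was less frequent (odds ratio 0.60), so its direction depended on the background. Against the same windows the RUNX call was lost (1.04), TFAP2 passed as more frequent (2.04), SOX and LEF/TCF as less frequent (0.79 and 0.80), and HNF4, GATA, HOX13-type and PBX motifs as less frequent (0.59, 0.55, 0.37 and 0.51). The NFI call was lost in the conservative list (5.01, Fisher's exact test, adjusted p = 0.371, 2875 windows).

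**Figure D4:**
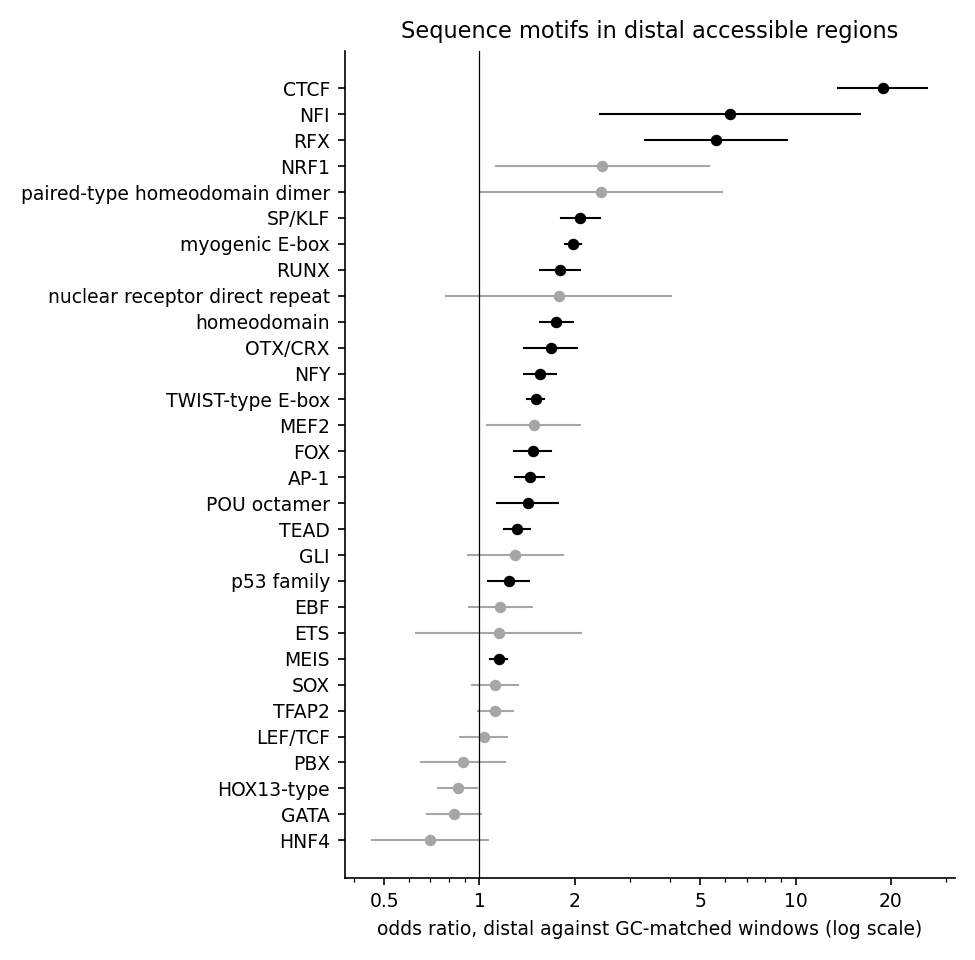
Odds ratio of each motif found in at least 10 distal windows (x axis, log scale) between distal and GC-matched windows, with 95% intervals. Black marks an adjusted p below 0.05 and grey the rest. CTCF has the highest value, 18.9, against 11.7 in replicate 1 alone, where RFX had 11.4.

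An E-box and a homeodomain site occurred together at particular distances. A composite of this kind has been described at enhancers of cranial neural crest. TAATT followed by 5 bp and CAGATG was found in 19 distal windows and 0 matched windows (Fisher's exact test, adjusted p = 0.000299). AATTA followed by 4 bp and CAGATG was found in 14 against 1 (Fisher's exact test, adjusted p = 0.0346), and CAGATG followed by 5 bp and AATTA in 15 against 1 (adjusted p = 0.0245). In 6 windows the first 2 arrangements were the same site, a full TAATTA, which left 8 windows at the second alone. The 3 arrangements covered 42 windows. The same E-box with TAATT 27 bp upstream was less frequent, in 5 against 33 windows (odds ratio 0.15, Fisher's exact test, adjusted p = 0.000299). This rests on a high count in the matched windows, where random spreads of the pairs reached at most 12. Matched windows were chosen on GC and not on repeats, so no loss in distal regions follows from it.

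Named after their values were seen, the 6 windows with the full site lay nearest to Atp2b1, Efemp1, P3h2, Cpn2, Robo2 and Peg10. Others lay 232 kb from Sox9 (chromosome 11, 113014230 to 113014430), 36.8 kb from Lhx8 (chromosome 3, 154367391 to 154367591) and 314 kb from Tgfbr2 (chromosome 9, 116489468 to 116489668). The numbers of windows are small. By Fisher's exact test 0 arrangements passed as more frequent in the conservative list and in replicate 2 alone (1 and 2 of 142 at an unadjusted p under 0.05 in either direction). In replicate 1 alone TAATT with 5 bp passed (15 against 1, Fisher's exact test, adjusted p = 0.0367). TAATT 27 bp upstream passed as less frequent in the conservative list (0 against 14 windows) and in replicate 1 alone (4 against 24), and not in replicate 2 alone.

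**Figure D5:**
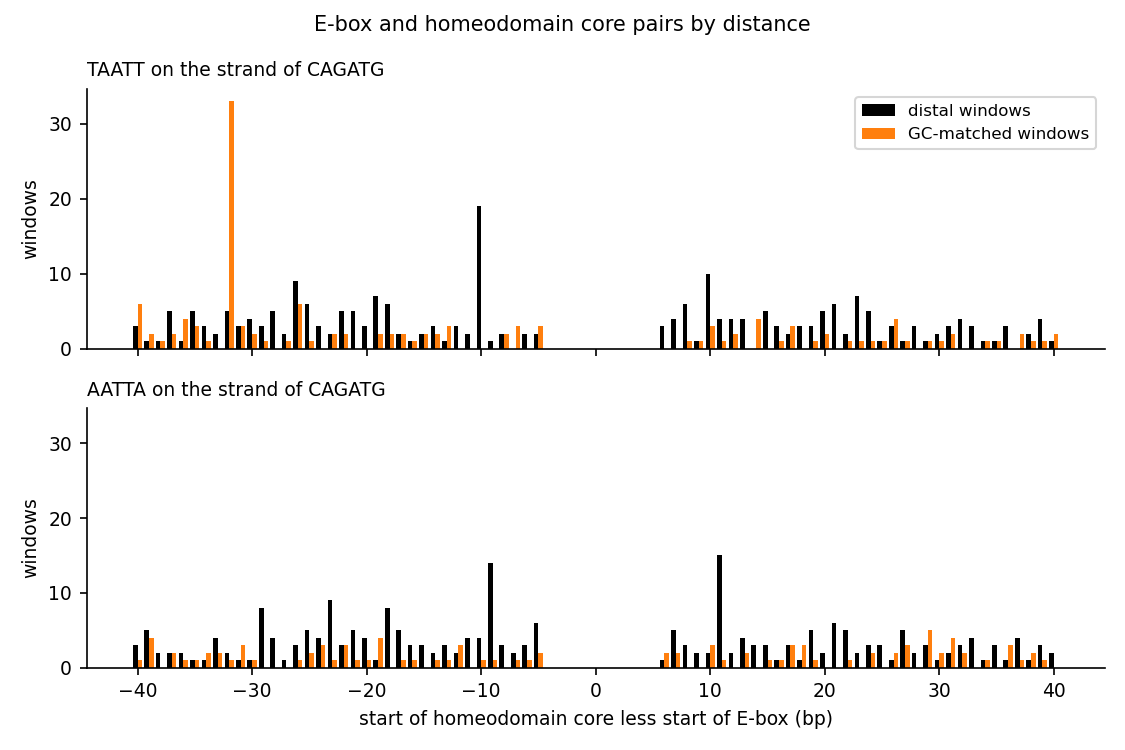
Number of windows (y axis) with CAGATG and a homeodomain core by start-to-start offset (x axis, bp, negative where the core lies upstream), with TAATT (top) or AATTA (bottom) on the E-box strand. Black bars are distal windows and orange bars GC-matched windows. Distal windows stand out at −10 (19), −9 (14) and 11 (15), and matched windows at −32 (33).

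The 2 pools showed no difference in the lineages their own regions lay at. Replicate 1 had 10595 regions (36.9%) that touched no region of replicate 2's ranked list and replicate 2 had 7806 (30%) in the other direction. These were weaker than shared ones, with median fold enrichments of 3.51 against 5.65 in replicate 1 and 3.38 against 5.23 in replicate 2, and were less often promoters (14.4% against 66.2%, and 17.6% against 66.4%). By Fisher's exact test, 0 of 18 lists differed between the 2 sets (lowest adjusted p = 0.824, 0 lists at an unadjusted p under 0.05). Erythroid genes had 7 regions in replicate 1 alone and 2 in replicate 2 alone, an odds ratio of 2.58 with an interval of 0.536 to 12.4, and macrophage genes 3 and 6 (0.368, 0.0921 to 1.47). Such intervals do not exclude sizeable differences in small lineages. This test compares these 2 libraries, not conditions.

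Region density was highest on chromosome 11, with 20.8 regions per Mb and 13.4 protein-coding genes per Mb, and lowest among autosomes on chromosome 14, with 11.6 regions per Mb. Chromosome X had 4.81 regions per Mb and 5.54 genes per Mb, where chromosome 12, with 5.35 genes per Mb, had 13.5 regions per Mb. Chromosome Y had 0.174 regions per Mb (16 regions, 10 and 12 in replicates 1 and 2 alone). In replicates 1 and 2 alone the values were 3.89 and 3.85 for X, 16.8 and 14.7 for chromosome 11 and 8.16 and 7.70 for chromosome 14. No test was made.

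The regions with the highest fold enrichment were short and 8 of 10 lay between genes. The highest, 54.8-fold at chromosome X, 143482936 to 143483180, lay 35531 bp from the nearest TSS, of Pak3. It was followed by regions at 48.0-fold (chromosome 2, 69355471 to 69355735, nearest gene Abcb11), 41.0-fold (chromosome 2, 3964419 to 3964690, Frmd4a), 40.7-fold (chromosome 10, 96077546 to 96077951, Gm5426) and 36.3-fold (chromosome 5, 60042765 to 60043105, G6pd2). The others, from 28.9-fold to 23.7-fold, were nearest to Galc, Tyrp1, Nxph1, Lars2 and Myl12b, of which the region in Lars2 was exonic and that nearest Myl12b intronic. Of these 10 regions 6 held sequence that matches mitochondrial DNA.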

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

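Of the tests in this part, those of the CpG content of Hox promoters, of filtering of the peak list, of sequencing depth and of copies of part of a region were chosen only after the result was seen. The other tests were set beforehand. So were the CpG-matched lists themselves, and only reading them as a test of CpG content came after. With 1 group of 2 pools there was no biological difference to set against the technical ones, so no biological explanation was tested.

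Peaks were also deposited on sequences outside the 21 chromosomes, which no comparison used. The ranked list of replicate 1 held 118 such peaks and that of replicate 2 held 124, each on 19 sequences, where a count of 0 would leave nothing to report. Their median fold enrichments were 3.0 and 3.5 and their highest 24.1 and 26.0. The filtered lists held 0 in each library. These sequences are unplaced or unlocalised parts of the assembly, no gene was assigned to them and no further test was made.

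The regions of highest fold enrichment resembled mitochondrial DNA. Of the 10, 6 aligned to the mitochondrial genome and 0 of 100 other regions, matched to them, did (Fisher's exact test, p = 9.8e-08). The match covered 365 bp at 99.7% identity in the region nearest Galc, 352 bp at 97.4% nearest Gm5426, 336 bp at 97.6% nearest G6pd2, 353 bp at 94.9% nearest Tyrp1, 310 bp at 95.5% nearest Nxph1 and 129 bp at 100% nearest Abcb11. Mitochondrial DNA carries no nucleosomes and is abundant in ATAC-seq libraries, so reads from mitochondrial DNA placed on nuclear copies of it could account for these 6. Copies of most of a region in the nuclear genome were not the rule, as 1 of 10, nearest G6pd2, had at least 50% of its 31-base words elsewhere, against 2 of 100 (Fisher's exact test, p = 0.251). That minimum sets the count, and the regions nearest Lars2 and Myl12b lay under it at 46.4% and 41.1%. With a lower bar, 9 of 10 regions had more of their words elsewhere than 95% of matched regions. The median was 35.2% in the 10 regions against 0% in the matched ones. This bar was set from the matched regions, so their 5 of 100 above it was fixed in advance and no p-value is given. Reads shared with copies of part of the region in the nuclear genome could therefore have raised these 9. Among them are the 4 without a mitochondrial match, nearest Lars2, Myl12b, Frmd4a (20.7%) and Pak3 (17.2%).

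Hox promoters had fewer regions than 3 technical explanations would give, while depth, the calling threshold and filtering within a library stay open. For the CpG content of the promoters, 23.1% of the 39 were open and none of the 10000 matched lists had a share as low, a percentile of 0 (matched mean 84.4%, permutation, adjusted p = 0.0018). For filtering of the peak list between replicates, 30.8% (12 of 39) were open in the union of all 12 deposited lists, with 56872 regions, against 86.7% of matched promoters (permutation, p = 0.0002). The lowest deposited −log10 p was 2.00 in each of these lists, so whether a lower calling threshold would open more Hox promoters could not be examined. Each library's own lists had been kept in pseudoreplicates or ranked or cut by IDR, and no peaks from before these steps were at hand. The union therefore tests filtering between the libraries and not filtering within a library. For sequence shared between Hox paralogs that reads cannot be placed on, 1.63% of the 31-base words in the 30 promoters without a region occurred elsewhere in the genome, against 3.65% in 90 CpG-matched open promoters. CpG content, filtering between the 2 libraries and shared sequence each forbid the value found as the whole cause. For the sequencing depth of the libraries no value here decides, since depth is unknown. The open Hox promoters were 9 in the list of both libraries, 1.8 times the 5 of replicate 1 alone (4 in replicate 2 alone), while matched promoters were open at 79.2% in replicate 1 alone and 84.4% in the list of both. Weakly accessible Hox promoters missed at this depth, at this threshold or by filtering within a library could therefore be among the 30. What left these promoters without a region was not tested.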

How the results depend on the processing

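Matching on 50 bins of territory or of GC was chosen after seeing the data. For every change given here the cause was not tested, except that the conservative list and a single library hold fewer regions. No paired analysis was possible because there was 1 group. Depth is unknown, so what it limits could not be worked out.

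Of the promoter results by list 70 kept direction and side of the threshold, 7 became significant, 10 lost significance and 3 turned direction, passing in neither setting. The 3 were cartilage (29.4%) and neuronal genes (33.3%) in the conservative list and cartilage without replicate 1 (52.9%, and 58.8% without replicate 2). In the conservative list the open share was 56.0% for crest transcription factors, 64.1% for facial signalling genes and 20% for cardiomyocyte and for photoreceptor genes, which all lost significance, and 5.0% for muscle and 5.56% for endothelium, which gained it. With a 1000 bp window ectoderm (44.4%), bone (35.7%), erythroid (38.9%) and cardiomyocyte genes (33.3%) lost significance. With the 5'-most TSS only, crest transcription factors lost it (70.0%) and neuronal genes gained it (83.3%). Leaving out each replicate gave 25 to 30% for muscle and 16.7 to 27.8% for endothelium (gained) and 27.8 to 38.9% for erythroid genes (lost without replicate 2).

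Of the distal results 87 kept direction and side, 7 gained significance, 4 lost it and 10 turned direction, passing in neither setting. In the conservative list these were ectoderm (−0.0580), muscle (−0.0900), erythroid (−0.0157), glia and melanoblast (0.00214), hepatocyte (−0.0349), cardiomyocyte (−0.107) and photoreceptor genes (−0.0651), and counting all regions within 100 kb glia and melanoblast genes (0.00997). Leaving out each replicate gave −0.00691 to 0.0337 for muscle and −0.0815 to 0.0397 for erythroid genes. Counting all regions within 100 kb of the gene gave cartilage 0.66, bone 0.72, muscle 0.56 and endothelium 0.60 (gained) and housekeeping 0.47 (lost). Bone gained it with 50 bins of territory (0.54), and housekeeping lost it in the conservative list (0.0633). Leaving out each replicate gave 0.44 to 0.49 for cartilage and 0.24 to 0.40 for macrophage genes (gained without replicate 1), and 0.13 to 0.19 for housekeeping (lost in both).

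Shared regions of replicate 1 were 62.6% with any overlap, 53.2% with reciprocal 50% overlap, 76.4% between thresholded lists and 62% against the ranked list. For replicate 2 the first 3 were 69.6%, 58.8% and 85.8%. The rank correlation was 0.84 with reciprocal overlap. In the conservative list promoters made up 75.4%, introns 10.5%, intergenic DNA 12.1% and exons 1.95%. Leaving out each replicate gave 47.1 to 51.8%, 22.7 to 25.2%, 21.9 to 23.8% and 3.66 to 3.90%. With a 1000 bp window promoters were 43.5%, introns 26.9% and exons 3.41%.

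The number of motifs more frequent in distal windows was 9 in the conservative list. Less frequent were 9 against flanking windows, 1 in the conservative list, 1 with 50 bins of GC and 0 to 1 leaving out each replicate. Against flanking windows, whose GC was lower, the odds ratio went below 1 for homeodomain (0.60), MEF2 (0.39), FOX (0.92), POU (0.74), SOX (0.79), LEF/TCF (0.80) and the paired-type dimer (0.735). In the conservative list it did for MEIS (0.84), TFAP2 (0.729), MEF2 (0.833), LEF/TCF (0.807) and GLI (0.333), and with 50 bins of GC for YY1 (0.75), EBF (0.987) and LEF/TCF (0.964). Leaving out each replicate it was 0.333 to 3.0 for REST, 0.833 to 21 for the paired-type dimer, 0.965 to 1.05 for PBX and 0.761 to 1.25 for HNF4. Of the other single motif results 121 kept their side of the threshold and did not cross 1, 19 gained significance and 11 lost it. Pair arrangements passing as more frequent were 0 in the conservative list, 0 to 1 leaving out each replicate and 3 with 50 bins of GC. As less frequent 1 passed in each of these except without replicate 1 (0). The count of lists that differed between libraries was 0 with the pseudoreplicated lists too.

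Without flank the regions per 100 kb were 3.80 at Hoxa, 1.15 at Hoxb, 0.864 at Hoxc, 5.16 at Hoxd, 16.1 at Dlx1-Dlx2, 7.65 at Dlx3-Dlx4 and 26.7 at Dlx5-Dlx6. With 100 kb on either side, leaving out each replicate gave in the same order 0.328 to 0.655, 0.267, 0.633 to 0.95, 1.35 to 1.68, 2.29 to 3.66, 3.54 and 2.74.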

Other observations

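Of the tests in this part, the random spreading of the pairs over the arrangements was chosen only after the result was seen, and so were the comparison of promoter with distal windows and the motifs named from it.

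Promoter and distal regions carried different sequences. In 13994 promoter windows against 21097 distal windows, consensuses of promoter-binding factors were more frequent, with odds ratios of 51.7 for YY1, 14.1 for ETS, 13.0 for NRF1, 7.38 for SP/KLF (17.0% against 2.69%) and 4.26 for NFY. Motifs less frequent at promoters included several of developmental factors, with 0.22 for homeodomain TAATTA, 0.24 for the TWIST-type E-box (3.38% against 12.6%), 0.28 for RUNX, 0.33 for SOX and 0.36 for TEAD. CTCF (0.23), AP-1 (0.42) and p53 family motifs (0.43) were also less frequent at promoters, while TFAP2 (0.99), RFX (0.94) and POU motifs (1.06) did not pass by Fisher's exact test. These windows were not matched on GC content, so base composition was not separated from the motifs.

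Some genes without a region at a TSS lay in well-populated territories. The nuclear receptor genes Nr2f2 and Nr2f1 had 14 and 12 distal regions and Tnp1, which encodes a sperm transition protein and is the nearest gene across a territory of 527 kb, had 13. Olfr161 had 18. At Tnp1 and Olfr161, genes of sperm and of olfactory neurons, replicates 1 and 2 alone had 11 and 8, and 14 and 9, such regions. Assignment to the nearest gene thus gives them regions whose target is unknown.

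The pairs of E-box and homeodomain site were weighed in 2 steps. Over the other 139 arrangements the median odds ratio of distal to matched windows was 2.50 and the upper quartile 5.0. Of these, 1 passed as less frequent, TAATT 27 bp upstream. Base composition of the background windows could explain the general excess, although they were matched on GC decile (mean GC 53.1% against 53.7%). The homeodomain motif and the TWIST-type E-box were each more frequent on their own (odds ratios 1.75 and 1.51), and this was not separated from it. A general excess of pairs, spread evenly over the arrangements, did not account for 2 of them. These were TAATT with 5 bp before CAGATG, in 19 windows, and AATTA with 5 bp after it, in 15. The 479 distal pairs were spread at random over the 142 arrangements, and in 1 of 10000 spreads did the highest count reach 15. AATTA with 4 bp before CAGATG was left with 8 windows once the 6 with a full TAATTA were counted only at the first arrangement. The highest count reached 8 in 9726 of 10000 spreads, so a general excess of pairs could explain this arrangement. The spacing was uneven in matched windows too, where 0 of 10000 spreads of 227 pairs reached the 33 found at 1 arrangement (highest 12). An uneven spacing is therefore not particular to distal regions, and a general excess that is itself uneven is not excluded for any arrangement. A repeated element with closely similar copies did not carry most of the pairs, as 2 of 42 windows aligned to another of them. Only long alignments at high identity counted, so a short or diverged repeat would be missed and is not excluded. The hypothesis that the pairs lie near crest transcription factor and signalling genes was left undecided. Of the 42 windows 2 (4.76%) were nearest to such a gene, Lhx8 and Tgfbr2, against 421 of 21055 others (2.00%, odds ratio 2.45, 95% interval 0.59 to 10.2, Fisher's exact test, p = 0.206).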
